A study of Pimephales promelas with 20 samples.

How the data were processed

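Total RNA of whole testes from 20 tanks was hybridised to single-colour (Cy3) Agilent arrays, 1 array per tank, per the labels' protocols. RNA of both fish of a tank was pooled where both met the RNA quality criteria and otherwise came from 1 fish, per the labels, which do not say which tanks were pooled. Groups and replicate numbers were taken from the sample titles.

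The deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1, per the file headers, with a background-subtracted and detrended processed signal, median spot and background intensity, and flags of 0 or 1 of another kind for outliers, saturation and signal well above background. The authors also deposited a table of log2 values with 49894 rows, of which 45 are control probes. Set against the scanner values, its columns had slopes of 1.00 to 1.01 on log2 signal scaled by the 75th percentile and centred on each probe's median over the 20 arrays. Its direction and scale were thus settled from the values. Column medians of that table are given in the results tables, and it served as an alternative.

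From each array's 61053 non-control spots, outlier-flagged spots were left out, spots of one probe were averaged (8332 probes had several, at most 10), log2 was taken, and the log2 of the array's 75th percentile was subtracted. Of 49849 probes, 35 were left out because every spot was an outlier on some array and 5552 because they were well above background on fewer than 5 arrays, leaving 44262. A probe not well above background on any array of a group was given as a bound, against the higher of its own signal and the lowest signal among probes well above background on each array.

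Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means, all 20 arrays), with 6 contrasts, a moderated F test over the 3 contrasts against control and, separately, a slope on concentration. P-values were adjusted by Benjamini-Hochberg within each test, and an adjusted p under 0.05 was a call. Spread is between tanks. The design, the alternatives and the rule for named genes were fixed before the data were examined. Leaving out outlier-flagged spots was not part of that design and was added after an exploratory run. That rule took the largest changes among calls whose 5 exposed arrays all lay on the same side of the control mean (for the trend, the 720 mg/L arrays), and named no probe without a gene name. None of the probe or systematic names matched the gene table used here (0 matches), so the 32 fixed gene lists with 1069 symbols, among them the cell type markers, had no measured member and no list test was run. Instead up to 2 rising and 2 falling probes per comparison were printed by the same order. Any further call of a group comparison is described without its identifier, unless the probe was printed for another comparison. These probes were chosen after their values were seen.

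The arrays lay on 4 slides, told from the file headers, and each slide held control and exposed arrays. Slide 1 held control replicates 1 and 2, 192 mg/L replicate 1 and 720 mg/L replicate 1. Slide 2 held control replicate 3 and 383 mg/L replicates 1 to 3. Slide 3 held control replicate 4, 192 mg/L replicates 2 to 5, 383 mg/L replicate 4 and 720 mg/L replicates 2 and 3. Slide 4 held control replicate 5, 383 mg/L replicate 5 and 720 mg/L replicates 4 and 5. Highest and lowest correlations between arrays were 0.970 and 0.802, and no arrays held identical values.

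The alternatives were normexp background correction (offset 50, on median spot and background signal, since the files hold no mean signal), quantile normalization, median scaling, other filters, slide or replicate number as a block, other variance models and thresholds, array weights, the deposited table and each array left out. The fits were tested on simulated arrays with the real means and independent spreads of 44262 probes, 200 of them changed. For 192 mg/L against control, 26% of probes changed by 1 log2 unit and 88% of those changed by 3 were recovered. For 383 mg/L these shares were 16% and 90%, for 720 mg/L 16% and 88%, and for the trend 46% and 94%. In the same 4 runs 10, 10, 7 and 7 unchanged probes were called. All simulated groups had the same spread per probe. With fewer changed probes than 200 the adjusted threshold is stricter, so these shares may be too high for the real data.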

Results

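Gene expression was measured in whole testes of adult male fathead minnows (Pimephales promelas), a small freshwater fish widely used in toxicity testing. The fish had been kept for 21 days in water with NTO (3-nitro-1,2,4-triazol-5-one), a component of insensitive munitions, at measured concentrations of 0 (control), 192, 383 or 720 mg/L. Each of the 4 groups held 5 replicate tanks, and each tank gave 1 single-colour array, so that 20 arrays were compared. A further, lower concentration named in the design was not analysed here. The question was how testis transcripts differ along this series of concentrations. The array's probes carry contig and singlet identifiers without gene names, so each result below is given by probe, and no gene or pathway is named.

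The arrays differed in brightness and in how many probes they detected. The 75th percentile of signal ranged from 486 to 1139 units. Between 35695 and 43951 of 49849 probes were well above background, with both of the lowest values in the 720 mg/L group (35760 in replicate 4 and 35695 in replicate 5) on the same slide. On that slide the SD of the negative controls, a measure of background noise, was 3.71 to 7.73, against 2.11 to 3.13 on the other slides. The mean number of detected probes was 39336 ± 3324 at 720 mg/L and 42149 ± 1482 in control (SD, n = 5 each, exact two-sided permutation p = 0.159). No probe was saturated. The number of arrays limits the precision of every value below.

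**Figure D1:**
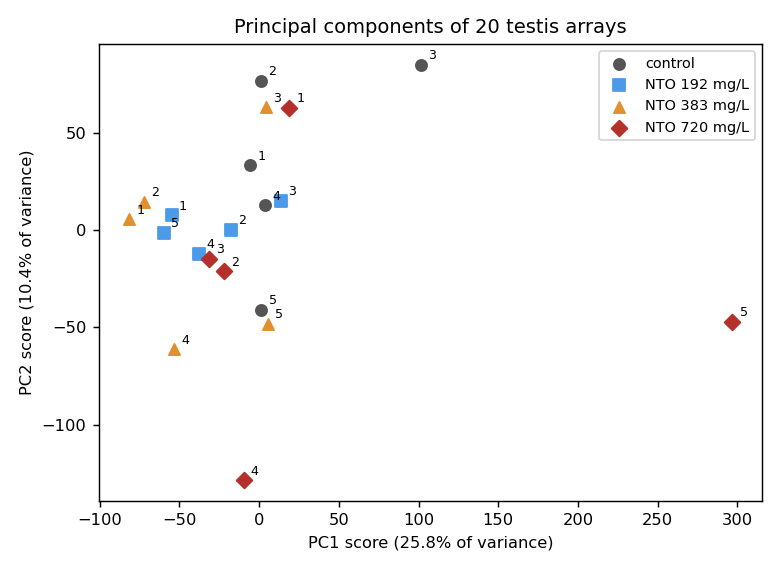
Scores of the 20 arrays on the first and second principal components of scaled log2 signal (25.8% and 10.4% of the variance), with colours and shapes for the 4 groups and numbers for replicates. Replicate 5 of 720 mg/L lies at 296.8 on the first component, where the next array, control replicate 3, lies at 101.6. The second component partly follows the slide. Control and exposed arrays of slides 1 and 2 lie at 5.55 to 84.8, those of slide 3 at -61.3 to 15.1 and those of slide 4 at -128.4 to -40.9.

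At 192 mg/L, 1 probe rose and 2 fell against control. SINGLET_4486 rose by 1.87 ± 0.28 on the log2 scale (SE, limma adjusted p = 0.0322), from -0.48 ± 0.53 to 1.40 ± 0.53 (SD, n = 5 each, log2 over the array's 75th percentile). SINGLET_28434 fell by 2.36 ± 0.34 (adjusted p = 0.0278), from -0.86 ± 0.83 to -3.22 ± 0.22. UF_Ppr_AF_117620 fell by 2.33 ± 0.32 (adjusted p = 0.0278), from -0.72 ± 0.77 to -3.05 ± 0.15. The profiles of both falling probes were similar over the 20 arrays, with an SD of their difference of 0.23, but this difference spanned 1.02 between arrays. At 383 and 720 mg/L the log2 folds of SINGLET_4486 were 1.27 and 1.09 and those of SINGLET_28434 were -1.23 and -0.78, and none of these passed. With the slide as a block the 3 log2 folds at 192 mg/L were 1.92, -2.56 and -2.57. Within slide 1 they were 1.93, -1.89 and -1.96, and within slide 3 they were 1.47, -3.15 and -2.97. Of 44262 probes tested, 2563 had an unadjusted limma p under 0.05, where 2213 would be expected with no change. This count was 4088 without 720 mg/L replicate 5, 4352 with only the 2 groups in the fit and 3913 with array weights. The share of lower probes among these was 62.7%, and 35.0% after quantile normalization and 42.2% after median scaling, so no general direction is given. The count of 3 calls went to 0 without any one of 192 mg/L replicates 1 to 4, 383 mg/L replicates 1 and 4, 720 mg/L replicates 3 and 4, or control replicates 4 and 5. It was 7 without 192 mg/L replicate 5 and 5 without control replicate 1, while the slide as a fixed block left 1 call and the fit of only the 2 groups left 0.

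At 383 mg/L, 3 probes fell against control and none rose past the threshold. UF_Ppr_AF_106353, at 91.5 times the 75th percentile in control, fell by 2.75 ± 0.35 (adjusted p = 0.00634), from 6.51 ± 0.64 in control to 3.76 ± 0.48. UF_Ppr_AF_106752 was well above background on 4 of 5 control arrays and not well above background on any 383 mg/L array. It was therefore at least 2.63-fold lower there (adjusted p = 0.00634), with measured means of -4.40 ± 0.55 and -7.46 ± 0.72. The third called probe fell by 1.61 ± 0.24 (adjusted p = 0.0312). The rising probe of smallest p, SINGLET_25116, had a log2 fold of 1.43 ± 0.23 and missed the threshold (adjusted p = 0.0507). With the slide as a block UF_Ppr_AF_106353 had a log2 fold of -2.55, and within slides 2, 3 and 4 the differences were -2.19, -3.13 and -2.97. For the third probe the block gave -1.75, and these slides gave -1.82, -2.68 and -1.30. UF_Ppr_AF_106752 has only its bound, so no value per slide is given. At 192 and 720 mg/L the log2 folds of UF_Ppr_AF_106353 were -1.42 and -1.92, neither of which passed. At an unadjusted limma p under 0.05 there were 6609 probes, 2410 higher and 4199 lower than control. The share of lower probes among these, 63.5%, was 39.0% after quantile normalization, 38.4% after median scaling and 73.2% after normexp correction. Normexp also moved the median of all probes to -0.17. The count of 3 calls was 108 without 720 mg/L replicate 5, 59 without 383 mg/L replicate 5, 20 without 720 mg/L replicate 4 and 14 without control replicate 1. It was 6 without 192 mg/L replicate 5 or control replicate 3, 5 without 720 mg/L replicate 2, and 5 with the slide as a fixed block.

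At 720 mg/L, 1 probe rose and 3 fell against control. SINGLET_36486 rose by 1.21 ± 0.19 (adjusted p = 0.035), from -3.25 ± 0.30 to -2.04 ± 0.21. CONTIG8922 fell by 2.25 ± 0.33 (adjusted p = 0.0307), from -1.53 ± 0.54 to -3.78 ± 0.70, with 4 of 5 arrays well above background at 720 mg/L. UF_Ppr_AF_111701 fell by 2.06 ± 0.28 (adjusted p = 0.022) and was well above background on all 5 control arrays but on 1 of 5 arrays at 720 mg/L. The third falling probe fell by 1.97 ± 0.28 (adjusted p = 0.0223). With the slide as a block the log2 folds of SINGLET_36486, CONTIG8922 and UF_Ppr_AF_111701 were 1.21, -2.25 and -2.15. Within slides 1, 3 and 4 those of SINGLET_36486 were 1.16, 1.38 and 1.29, and those of CONTIG8922 were -2.23, -2.12 and -2.24. Those measured for UF_Ppr_AF_111701, mostly undetected at 720 mg/L, were -2.14, -1.81 and -2.39. The third falling probe stood at -1.91 with the block and at -1.48, -2.24 and -1.94 within slides. At an unadjusted limma p under 0.05 there were 6012 probes, 1698 higher and 4314 lower. The lower share of 71.8% was 58.3% after quantile normalization and 60.7% after median scaling. The count of 4 calls went to 0 without 720 mg/L replicate 4 or without any one of control replicates 2 to 5. It was 23 without 720 mg/L replicate 2, 17 without control replicate 1, 11 without 383 mg/L replicate 4 and 7 without 720 mg/L replicate 3. It was 2 without 192 mg/L replicates 1 or 2, or 383 mg/L replicates 2 or 5, and 7 with the slide as a fixed block. It was 0 with array weights, with only the 2 groups in the fit and over probes well above background on all arrays (a filter that removes the 3 falling probes), and 1 with normexp correction.

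**Figure D2:**
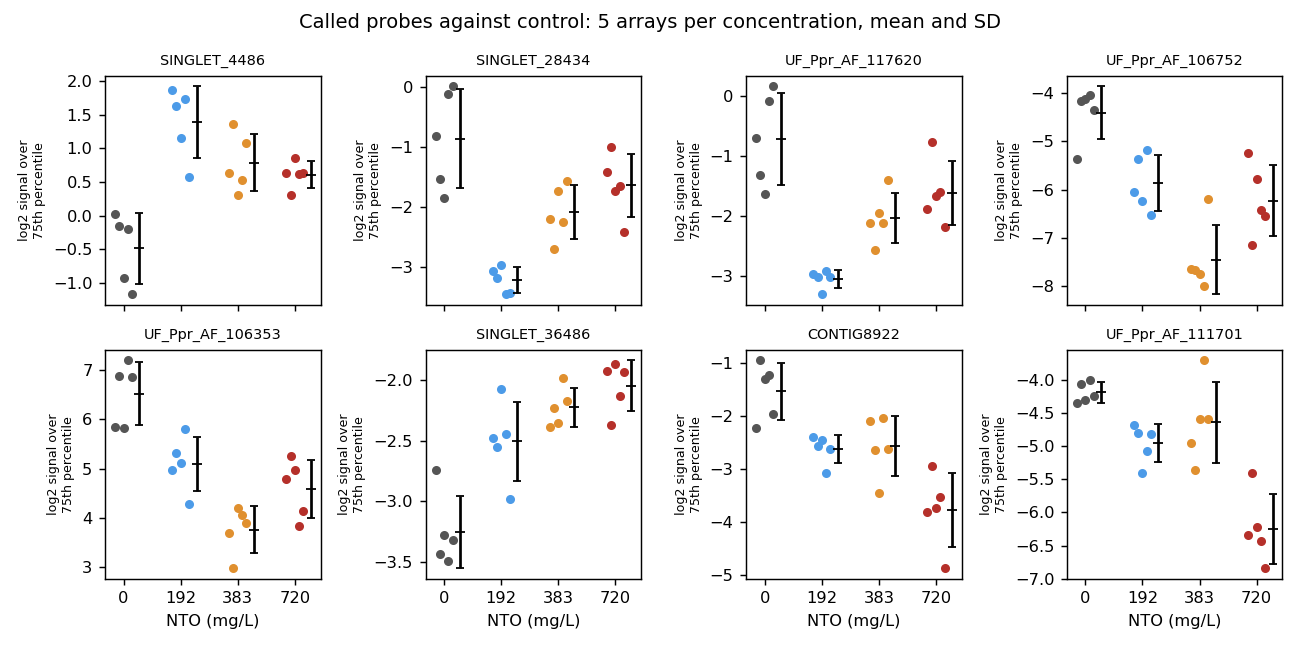
Scaled log2 signal (vertical axis, log2 over the array's 75th percentile) of 8 called probes at each NTO concentration in mg/L (horizontal axis). Points are single arrays, 5 per concentration, and bars are the mean and SD beside them. SINGLET_36486 moves from -3.25 in control to -2.04 at 720 mg/L.

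Along the concentration series, the slope on concentration passed the threshold for 46 falling and 4 rising probes. Whether the change was linear in shape was not tested. Over the 46, the median fitted change from 0 to 720 mg/L was -1.72, ranging from -3.15 to -0.88. At 720 mg/L, 23 of the 46 were well above background on all 5 arrays, 22 on 1 to 4 arrays and 1 on none, so that changes of the dimmer probes are less certain. Over the 23 the median fitted change was -1.34, ranging from -2.90 to -0.88. A choice by detection at 720 mg/L itself favours smaller falls. The undetected probe was at least 1.83-fold lower than control. Over all 46, the median difference from control was -0.41 at 192 mg/L, -0.97 at 383 mg/L and -1.75 at 720 mg/L (-1.59 with the undetected probe at its bound), and all 46 lay below control at each concentration. In 45 of the 50 the group means followed the order of concentration. Selection on the slope itself favours such an order and means below control. UF_Ppr_AF_109705, well above background on 3 of 5 arrays at 720 mg/L, fell by 3.15 ± 0.52 (limma adjusted p = 0.0399) and UF_Ppr_AF_115076 fell by 2.90 ± 0.49 (adjusted p = 0.0399). SINGLET_5718 rose by 1.14 ± 0.22 and SINGLET_36486 by 1.12 ± 0.21 (adjusted p = 0.0423 for each). With the slide as a block these fitted changes were -3.28, -2.89, 1.102 and 1.15. All 50 adjusted p-values lay between 0.0399 and 0.05, and the count depended on single arrays. It was 0 without 192 mg/L replicates 1, 2 or 5, 720 mg/L replicate 4, or control replicates 2, 4 or 5. It was 1 without 720 mg/L replicate 5 or control replicate 1, 7 without control replicate 3, 19 without 383 mg/L replicate 5 and 25 without 192 mg/L replicate 4. It was 592 without 720 mg/L replicate 3, 218 without 383 mg/L replicate 4 and 79 without 720 mg/L replicate 1. With the slide as a fixed block no probe passed (5987 at an unadjusted limma p under 0.05), nor with array weights, and normexp correction left 6.

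**Figure D3:**
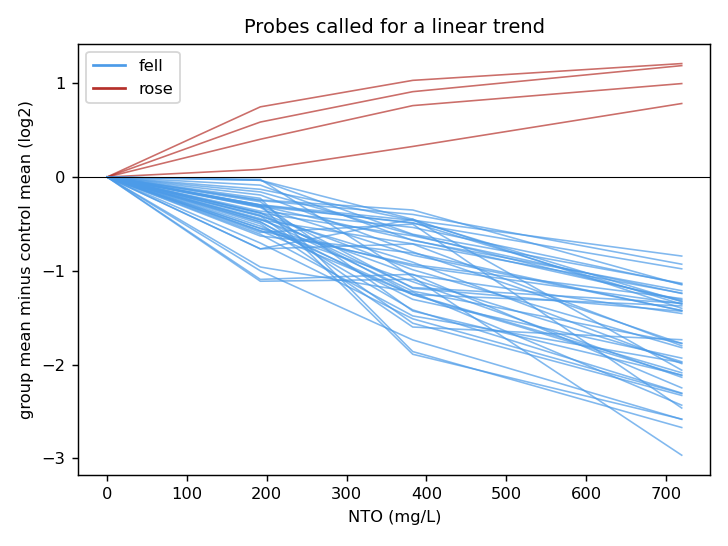
Group mean minus control mean (log2, vertical axis) against NTO concentration in mg/L (horizontal axis) for the 50 probes called for a linear trend, 1 line per probe, 46 falling and 4 rising. The median falling probe lies at -0.41, -0.97 and -1.75 at the 3 concentrations, and the probes were selected for a trend.

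The exposed groups were also compared with each other. Between 383 and 192 mg/L 3 probes were lower at the higher concentration: CONTIG8739 fell by 2.42 ± 0.30 (adjusted p = 0.00888), UF_Ppr_AF_103360 fell by 2.15 ± 0.32 (adjusted p = 0.0378) and the third, SINGLET_10878, fell by 1.63 ± 0.25 (adjusted p = 0.0378). Between 720 and 383 mg/L 3 probes rose. UF_Ppr_AF_103360 rose by 2.56 ± 0.32 and SINGLET_10878 by 1.93 ± 0.25 (adjusted p = 0.00502 for each), and the third, well above background on 2 of 5 arrays at 383 mg/L, had a measured rise of 1.63 ± 0.24 (adjusted p = 0.0325). UF_Ppr_AF_103360 and SINGLET_10878 had their lowest group means at 383 mg/L, at -4.73 ± 0.96 (4 of 5 arrays well above background) and -3.81 ± 0.62 against -3.16 ± 0.08 and -3.03 ± 0.29 in control. Neither difference from control passed (adjusted p = 0.0819 and 0.191). Within slide 3, CONTIG8739 and UF_Ppr_AF_103360 differed by -2.30 and -2.05 between 383 and 192 mg/L, and with the slide as a block by -1.74 and -1.92. The third probe of that comparison stood at -1.63 within slide 3 and at -1.37 with the block. Between 720 and 383 mg/L the differences of UF_Ppr_AF_103360 were 2.25 within slide 3 and 1.40 within slide 4, and 2.19 with the slide as a block. Those of SINGLET_10878 were 2.06, 0.96 and 1.58, and those measured for the third rising probe, mostly undetected at 383 mg/L, 1.25, 0.68 and 1.29. With the slide as a fixed block neither comparison kept a call past the threshold (2669 and 3055 probes at an unadjusted limma p under 0.05), nor did the fits of only the 2 groups. Without the block 1641 probes had an unadjusted p under 0.05 between 383 and 192 mg/L, below the 2213 expected with no change. Without 383 mg/L replicate 5 each comparison gave 36 calls. Between 383 and 192 mg/L there were 0 calls without 192 mg/L replicates 3 or 4 or 383 mg/L replicate 3, and 5 without 720 mg/L replicate 1. There was 1 call without 192 mg/L replicates 2 or 5, 383 mg/L replicates 1, 2 or 4, 720 mg/L replicates 2 to 5, or control replicates 2, 3 or 5. Between 720 and 383 mg/L there were 5 without 720 mg/L replicate 4 and 6 without control replicate 4. The number at an unadjusted p under 0.05 in this comparison, 3126, was 1771 without 720 mg/L replicate 5, 1915 without 383 mg/L replicate 1 and 4885 without 720 mg/L replicate 3. Between 720 and 192 mg/L limma called 0 probes, with 3697 at an unadjusted p under 0.05. That number was 5592 without 720 mg/L replicate 3, 2445 without 720 mg/L replicate 5 or 192 mg/L replicate 5, and 2223 with the slide as a fixed block, where 2213 would be expected with no change. The falling probe of smallest p, UF_Ppr_AF_109705, had a log2 fold of -2.94 ± 0.53 (adjusted p = 0.382).

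The moderated F test, which asks whether the 4 group means differ at all, called 6 probes. Each was among the probes named above, with CONTIG8739 at an adjusted p of 0.0154. CONTIG8739, UF_Ppr_AF_103360 and SINGLET_10878 passed in no single comparison with control, so a call here need not be a difference from control. The count was 0 without 383 mg/L replicates 1 or 3, 2 without 383 mg/L replicate 2, 3 without 192 mg/L replicate 2 or control replicates 2, 4 or 5, 13 without control replicate 1 and 44 without 383 mg/L replicate 5. It was 0 with the slide as a fixed block (5322 at an unadjusted limma p under 0.05).

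Fold changes against the shared control correlated across probes, which are not independent replicates. Pearson's r was 0.70 between 192 and 383 mg/L, 0.43 between 192 and 720 mg/L and 0.51 between 383 and 720 mg/L. Unchanged groups simulated against shared controls gave 0.50. The simulation gave all groups the same spread per probe. The measured median SD was 0.46 in control, 0.31 at 192, 0.41 at 383 and 0.59 at 720 mg/L, so the simulated values are only rough yardsticks. The covariances were 0.20, 0.12 and 0.16, beside a simulated 0.098 in each pair. When the controls were split so that each concentration had its own control arrays, the median r over 20 splits was 0.26, 0.019 and 0.10. Among probes at an unadjusted p under 0.05, 888 were lower and 516 higher at both 192 and 383 mg/L, and 2089 were lower and 737 higher at both 383 and 720 mg/L. Unrelated lists of the same sizes would share 153, 52.0, 409 and 92.5. Simulated unchanged groups shared 238, 234, 243 and 232, but their lists differed in size from the real ones (1113 lower probes at 383 mg/L against 4199), so these are no direct yardstick. As given above, the main direction at 192 and 383 mg/L turns with the scaling, and at 720 mg/L it does not.

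**Figure D4:**
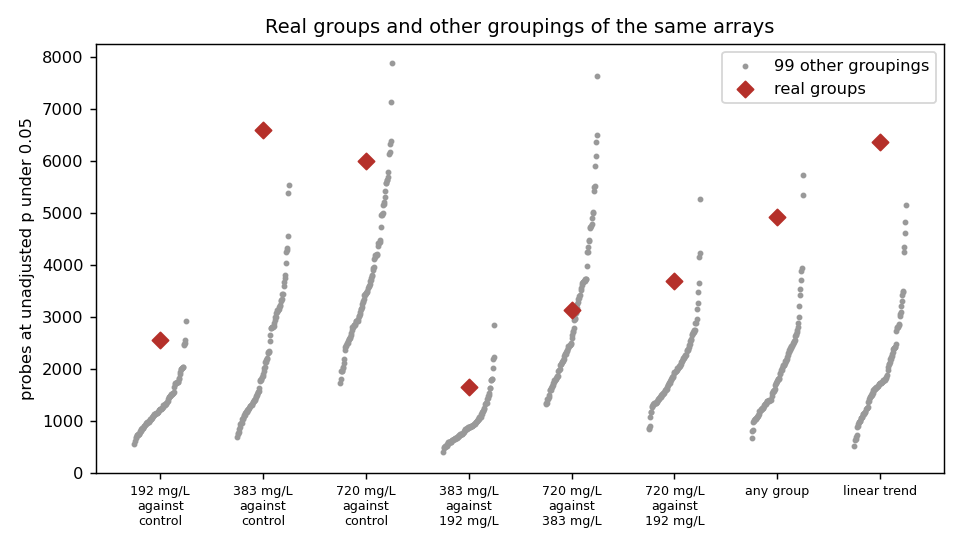
Number of probes at an unadjusted p under 0.05 (vertical axis) for the real groups (diamonds) and for other groupings of the same arrays (grey points) in each comparison (horizontal axis). At 383 mg/L against control the real count is 6609 and the highest other is 5537.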

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

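In 100 groups of 5 values (array measures and called probes), the gap between the most extreme array and its nearest neighbour was compared with the group's range. It exceeded the 95% limit of Dixon's test in 9 groups, where chance flags about 1 in 20. The first 3 tests below were set out before their results were seen.

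The array of 720 mg/L replicate 5 stood apart, with a first-component score of 296.8 (others of its group -31.7 to 18.7) and a distance from the rest of its group of 1.56 log2 units (others 0.74 to 0.94). A failed hybridisation is argued against by its spike-in slope of 0.967 and R squared of 0.988, both inside the ranges of the other arrays (0.862 to 1.05 and 0.941 to 0.994). The scaling is argued against as well, since after quantile normalization its distance was still 2.09 times the median distance. A dimmer array or sample stays open, since quantile normalization cannot restore signal lost to background. This array had the fewest probes well above background (35695) and 23.6% of its signal in the 100 brightest probes, where the next highest share was 21.6%. Background noise stays open too. The SD of the negative controls was 4.82 on this array and 3.71 to 7.73 on its slide, against 2.11 to 3.13 on the other slides. RNA quality of the sample was not tested. Another cell make-up of that sample stays open: 4924 probes differed by 4-fold or more from the mean of the other 4 arrays, where the median array had 1178 and the highest other 2160. Of these 3181 were higher and 1743 lower, and 31.6% of the lower ones were well above background on this array, against 94.7% on the other 4, so part of the count is loss of detection. Without gene names no marker could be tested. An effect of the concentration in that tank alone was not tested.

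Control replicate 3 scored 101.6 on the first component, where the other controls scored -5.62 to 3.86. The spike-in R squared was 0.953 in control replicate 5 (others at least 0.985) and 0.941 in 720 mg/L replicate 1 (others at least 0.980). UF_Ppr_AF_106752 stood at -5.36 in control replicate 1 (others -4.35 to -4.04) and at -6.20 in 383 mg/L replicate 5 (others -8.01 to -7.65). At 383 mg/L it was not well above background on any array, so the second of these flags compares undetected signals. SINGLET_36486 stood at -2.74 in control replicate 1 (others -3.50 to -3.28). UF_Ppr_AF_117620 stood at -3.31 in 192 mg/L replicate 3 (others -3.03 to -2.91).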

How the results depend on the processing

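The sign of every probe printed in the report stayed the same under each alternative run (for a probe undetected in a group the size is only a bound). These probes were picked from the same data by fold, p and the side on which their arrays lay. A change of sign was thus unlikely from the start, and its absence is little support. Slides 2, 3 and 4 also held only 1 control array each. A call was lost in 287 of the values recomputed for these probes and gained in 14. Another 13, all differences within 1 slide, moved by at least the probe's residual SD, and 567 kept their call or size. Counts of calls were small and moved readily. The cause was not tested except where the setting itself gives it. Leaving out both 720 mg/L arrays of low detection was chosen after seeing the data. The main counts were 3 (192 mg/L), 3 (383 mg/L) and 4 (720 mg/L) against control, 3 (383 against 192), 3 (720 against 383), 0 (720 against 192), 6 (any group) and 50 (trend).

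Without single arrays the counts ranged from 0 to 7 at 192 mg/L, 2 to 108 at 383 mg/L, 0 to 23 at 720 mg/L, 0 to 36 for 383 against 192, 2 to 36 for 720 against 383, 0 to 44 for any group and 0 to 592 for the trend, and stayed at 0 for 720 against 192. Without both 720 mg/L arrays of low detection they were 194 at 383 mg/L, 0 at 720 mg/L, 1 for 383 against 192 and 0 for the trend.

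Normexp correction gave 17 at 383 mg/L, 1 at 720 mg/L, 15 for 383 against 192, 22 for 720 against 383, 27 for any group and 6 for the trend. Quantile normalization gave 5 for 383 against 192, and median scaling 10 for the trend. With no filter there were 5 for 720 against 383 and 7 for the trend. Over the 30199 probes well above background on all arrays there were 24 at 383 mg/L, 0 at 720 mg/L, 14 for any group and 87 for the trend. The slide as a fixed block gave 1, 5 and 7 against control, and 0 for 383 against 192, 720 against 383, any group and the trend. As a random block (correlation 0.058) it gave 10 at 383 mg/L and 1 for 383 against 192. With only the compared groups in the fit there were 0 at 192 mg/L, 720 mg/L, 383 against 192 and 720 against 383. Trend and robust variance gave 16 at 383 mg/L, 8 at 720 mg/L and 145 for the trend. Array weights gave 0 at 720 mg/L, 41 for 383 against 192, 5 for 720 against 383 and 0 for the trend. Rank of concentration gave 254 for the trend.

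At an adjusted p under 0.1 there were 57 at 383 mg/L, 245 at 720 mg/L, 16 for 720 against 383, 31 for any group and 786 for the trend. At an unadjusted p under 0.05 with a fold of at least 1.5 there were 2020, 5035 and 4780 against control, 1343 for 383 against 192, 2542 for 720 against 383, 2937 for 720 against 192 and 4815 for the trend.

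The replicate number as a block, alone or with the slide as a random block, gave 0 at 192 and 383 mg/L, 1 at 720 mg/L, and 0 for 383 against 192, any group and the trend. No clear pairing by number was seen, but none was tested. Deviations of same-numbered arrays correlated from -0.27 to 0.30, with a mean of 0.048 against -0.011 for different numbers. Of 30 same-numbered pairs 12 were over 0.1, and 5 of 20 arrays correlated best with their own number. Main counts at an unadjusted p under 0.05 alone were 2563 (192 mg/L), 1641 (383 against 192), 3126 (720 against 383) and 3697 (720 against 192). With only the compared groups they were 4352, 2704 and 1776 in the first 3 of these, and with array weights 3913, 3167 and 2000. Without both 720 mg/L arrays of low detection they were 4270 at 192 mg/L, 1614 for 720 against 383 and 1745 for 720 against 192. Over probes well above background on all arrays there were 1648 at 192 mg/L, and the slide as a fixed block gave 2669 for 383 against 192 and 2223 for 720 against 192. Other settings, apart from single arrays left out, kept these counts and those of calls within 1.5 times the main count. The list tests and 1 probe per gene could not be run without gene names. Signal over background limits probes not well above background at 383 or 720 mg/L to bounds.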

Other observations

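The tests of the 192 mg/L spread were chosen only after that result was seen, as were the counts of groupings for the 3 comparisons with control and the trend. The requirements that the slide difference exceed its spread, that a missed threshold leave the probe sets undecided, and that a real count of 0 decide nothing, were also set after the values were seen.

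The 192 mg/L arrays lay closer together than the control arrays, with a mean distance from the rest of the group of 0.61 ± 0.04 against 0.81 ± 0.11 log2 units (SD, n = 5 each, two-sided permutation p of the distances = 0.00794, adjusted p = 0.0238 over 3 comparisons, the smallest p possible before adjustment). The permutation exchanged the finished distances. Those of 1 group share arrays and are not independent, so this p is not exact for the spread. Less noise between spots of an array is argued against, since the CV of repeated spots reached 4.31% on a 192 mg/L array and spanned 3.66% to 4.29% in control. Measurement noise between arrays, which this CV does not hold, was not tested. Sharing a slide stays open: the fifth array was 0.040 farther from the 4 on one slide than these were from each other, with an SD of 0.021 over its 4 distances. Its mean distance to them was 0.796, below the 0.932 of the closest control arrays on different slides. All of this rests on 1 array of 192 mg/L. In the other groups 6 pairs on one slide lay 1.06 ± 0.34 apart and pairs on different slides 1.09 ± 0.23 (SD), against 0.757 among the 4 arrays. The 6 ranged from 0.756 to 1.71, and without 720 mg/L replicate 5 the means were 0.928 ± 0.148 and 1.02 ± 0.09, so they do not decide it. A more uniform testis state at this concentration was not tested.

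The probes called for a trend mostly fell. The slide as the whole cause is argued against, since with it as a block the median fitted change of the 46 falling probes was 1.02 times that without it (-1.75 against -1.72, median SE 0.300 and 0.292). The calls ended there while the changes did not shrink. Without replicate 5 of 720 mg/L the median fitted change was 0.945 times that with all arrays (-1.63), so the shrinkage predicted for it was not seen. The 46 were chosen with this array in the fit, which made a large shrinkage unlikely, and without it the trend had 1 call. Its share in the trend calls thus stays open. Deviations of the 46 from their group means had a mean correlation of 0.208, against at most 0.135 in 1000 random sets of the same size, the excess predicted for few independent signals. The random sets were drawn without regard to direction while all 46 fell, which favours a higher correlation of the 46. The deviations also include replicate 5 of 720 mg/L. Whether there were fewer independent signals than 46 thus stays open. An effect of the concentration stays open.

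Among the 5000 most variable probes, 8 sets that vary together within groups were compared with control at each concentration. The lowest adjusted exact permutation p over 24 tests was 0.698, so no set passed, as had been set out for sets that do not differ. That criterion was too weak: with 5 arrays per group no p lies under 0.00794, which does not pass over 24 tests unless several reach it, so a difference of these sets stays undecided.

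Whether chance alone gives such counts was examined with 100 groupings per result, the real one included. For the trend, 1 grouping gave as many calls (50, highest other 1) and 1 as many probes at an unadjusted p under 0.05 (6366, highest other 5150). Chance alone is thus argued against for both in this draw, as far as arrays may be exchanged freely. No verdict here was adjusted for the number of counts examined, so 2 to 4 groupings of 100 are only weak evidence. The groupings were drawn without regard to the slide, and with the slide as a fixed block the trend had 0 calls and 5987 probes at an unadjusted p under 0.05. The highest other count depends on the draw. An earlier exploratory draw, made before outlier-flagged spots were left out and not kept, held a grouping with many times the real number of calls. It also held at least 1 other grouping with as many probes at an unadjusted p under 0.05 as the real one. On the same terms chance is argued against for the calls at 192 mg/L (1 grouping, 3 calls, highest other 1). More weakly it is argued against for those at 383 mg/L (3 groupings, 3 calls, highest other 15), 720 mg/L (3 groupings, 4 calls, highest other 146), 383 against 192 (2 groupings, 3 calls, highest other 31) and any group (2 groupings, 6 calls, highest other 623). These 5 results had 1, 5, 7, 0 and 0 calls with the slide as a fixed block, so for 383 against 192 and any group the verdict leaves the slide open. Among unadjusted counts chance is argued against at 192 mg/L (2 groupings, 2563, highest other 2913), 383 mg/L (1 grouping, 6609, highest other 5537), 720 against 192 (4 groupings, 3697, highest other 5267) and any group (3 groupings, 4919, highest other 5724). With the slide block these counts were 2458, 8094, 2223 and 5322, and that of 720 against 192 was then near the 2213 expected with no change. Chance cannot be excluded for the unadjusted counts at 720 mg/L (7 groupings, 6012, highest other 7883), 383 against 192 (9 groupings, 1641, highest other 2844) and 720 against 383 (41 groupings, 3126, highest other 7642), nor for the calls of 720 against 383 (6 groupings, 3 calls, highest other 621). For the calls of 720 against 192 nothing can be said, since the real count was 0 (highest other 2) and all 100 groupings reach that.

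Some groupings gave many times the real count, and the reason was not tested. The grouping with 621 calls set the compared arrays of slides 1 and 2 with 720 mg/L replicate 3 against the rest. Another of that comparison, with 301 calls, set 383 mg/L replicates 1, 2 and 5 with 720 mg/L replicates 1 and 3 against the rest and did not follow the slide. The source of these large counts thus stays open. The grouping with 146 calls exchanged 720 mg/L replicate 5 with control replicate 1.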
